A study of Mus musculus with 20 samples.

How the data were processed

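The data were RNA-seq gene counts from primary mouse cardiac fibroblasts in culture, in 5 groups of 4 libraries. Per the labels' protocols, early-passage cells carrying a loxP-flanked Hyal2 gene were serum starved for 24 h, exposed to an adenovirus for 5 h and then kept for 48 h in medium with growth factor at 20 ng/mL. The adenovirus carried GFP as a control, Cre recombinase to delete exon 2 of Hyal2, or Hyal2 itself. The labels name TGFB in 2 of the groups; their wording leaves open whether the other cultures received bFGF in its place, so those groups are called cultures without TGFB here. Replicates 1 and 2 of every group are labelled female and replicates 3 and 4 male. The replicate numbers recur across the groups, and each number is treated as one cell isolate. The genotype label reads wild type although the treatment protocol names floxed cells.

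Per the labels' protocols, total RNA was extracted with Trizol, treated with DNase and made into libraries with a NEBNext Ultra II RNA kit. Per the submitters' processing notes, FastQC 0.10.1 and HTSeq 0.10.0 were used with the mouse build GRCm39 (mm39). The deposited values are raw counts of reads per Ensembl gene, not normalised by the authors. The aligner, the annotation release and the strand setting of the counting are not given in the sources used here. Reads of antisense or overlapping neighbours, such as Hyal3 and Naa80, and of near-identical gene copies may therefore be shared. Gene counts also do not show which exons the reads came from, so the deletion of exon 2 was not measured as such.

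All 20 columns of the count table matched a labelled sample, and 0 columns were left unmapped. Gene symbols were looked up by Ensembl identifier in an annotation of the earlier build GRCm38, used for names only, and no coordinates are given. Of 55414 identifiers, 52081 had a symbol; the others held 0.215% to 0.568% of the counts of a library. Library totals ranged from 38.6 to 104.8 M counts. A floor of 3 counts corresponds to 0.0286 to 0.0777 CPM (counts scaled to a common library size, here by the library totals), and this covers counting error only. The 10 most abundant genes took 10.1% to 13.0% of a library. No 2 replicates of a group held identical counts, and the chi-square per degree of freedom between replicates was at least 10.2 in all 30 pairs.

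Counts were tested with edgeR 4.0.16 in R 4.3.3 with the robust quasi-likelihood F test. One fit held all 20 libraries, with a mean per group, TMM factors and no block. Differences between the isolates, which pair the libraries across groups, therefore stayed in its error and can lower its number of calls. Calls with a replicate block are given as an alternative. Genes were kept by filterByExpr (minimum count 10 in at least 4 libraries, minimum total 15), which left 15624 of the 31062 genes with any count. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Standard errors (SE) of log2 fold changes were computed as the absolute log2 fold change divided by the square root of F. CPM values are normalised with the TMM factors, except those of Xist and the Y-linked genes and the floor of 3 counts, which are relative to the library totals. The sex difference in the TGFB effect was taken from a fit with a mean per group and sex, so that each mean rests on 2 libraries.

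The tests compared Cre with GFP, Hyal2 with GFP, GFP_TGFB with GFP, Cre_TGFB with GFP_TGFB and Cre_TGFB with Cre. The Cre by TGFB interaction, which is the difference between the Cre effects with and without TGFB, and the sex difference in the TGFB effect were tested as contrasts of the same kind. A total of 31 gene lists, covering pathways, matrix classes and markers of other cell types, were tested with camera of limma 3.58.1 at its preset correlation of 0.01 on log2 CPM with a prior count of 2, adjusted over the lists of a comparison. The same test with an estimated correlation passed 0 lists in any comparison at an adjusted p under 0.05; with the replicate block it also passed 0 in the 6 comparisons where the block was used for lists, which leaves out the sex difference. Its p is given beside each call, or, for calls that need the block, the p with the block, in places as a range over the lists. The self-contained test fry, which asks whether the genes of a list move one way on balance, was run beside it.

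The groups, tests, gene lists, the rule for the genes named and most alternatives were fixed before the data were examined. The rule takes Hyal2, the genes with the largest called change in each direction (at most 6, for the sex difference at most 3) with a mean of at least 5 CPM in the higher group and, in comparisons of groups, full separation of replicates, the members of each described list with the smallest p, and every tested gene of hyaluronan synthesis and turnover. Clone names were left out, 1 gene that the rule names is not reported here, and where no gene met the rule for largest changes the 3 higher and 3 lower genes with the smallest p were taken. Acta2, Postn, Col1a1, Col3a1, Sstr5, Stmn4, Gm19410, Ednrb, Cxcl10, Gbp5, Gsta3, Gsta4 and Slc25a22 (in Cre against GFP) were named outside the rule, after their values were seen. Markers of sex (Xist and 4 Y-linked genes) were compared with the labels.

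The replicate numbers pair the libraries, since the library names in the labels give each number 1 identifier shared by all groups. Deviations from the group means correlated at 0.24 to 0.712 between libraries of the same number in all 20 pairs, above the 0.1 asked for, and 18 of the 20 were best correlated with their own number. Alternatives were RLE size factors, no filter, a stricter filter, DESeq2 1.42.0, limma-voom, a replicate block, a fit of only the groups compared, library sizes without Hyal2 and mitochondrial genes, and leaving out each library in turn.

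The test was checked on simulated counts for the same 15624 genes. For each fold, 66 or 67 genes with a mean of at least 5 CPM in the control group were changed. For Cre against GFP with independent libraries it recovered 77.6% of genes changed by 1.5-fold, 94% of those changed by 2-fold and 100% of those changed by 4-fold. With libraries that share isolates, 82.1% of the 1.5-fold changes were recovered without a block and 92.5% with it. For Cre_TGFB against GFP_TGFB with independent libraries, 74.6% of the 1.5-fold changes were recovered. The adjusted threshold is easier to pass with that many changed genes than where few change. These shares therefore do not give the power of the real comparisons or of genes under 5 CPM. In the data Hyal2, at a log2 fold change of -1.98 for Cre against GFP, had an edgeR adjusted p of 0.0184.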

Results

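RNA-seq gene counts were obtained from 20 cultures of mouse cardiac fibroblasts, the main matrix-producing cells of the heart. The 5 groups of 4 cultures received a control virus (GFP), a Hyal2 deletion virus (Cre), a Hyal2 overexpression virus (Hyal2), or the GFP or Cre virus with TGFB (GFP_TGFB and Cre_TGFB). The 4 isolates behind each group were 2 female and 2 male. Mean library totals were 49.9 ± 14.1 M counts (SD, n = 4) in GFP, 70.6 ± 27.8 in Cre, 41.9 ± 3.2 in Hyal2, 48.9 ± 15.6 in GFP_TGFB and 59.9 ± 19.5 in Cre_TGFB. Xist, the RNA of the inactive X chromosome, lay at 175 to 317 CPM in the 10 female libraries and at most at 0.17 CPM in the 10 male ones. The Y-linked gene Ddx3y lay at 49.3 to 89.1 CPM in the male libraries and at 0 in the female ones, so all sex labels matched.

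The first principal component of log2 CPM held 71.1% of the variance and parted the cultures with TGFB from those without it. The second held 10.5% and parted the 10 female from the 10 male libraries.

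**Figure D1:**
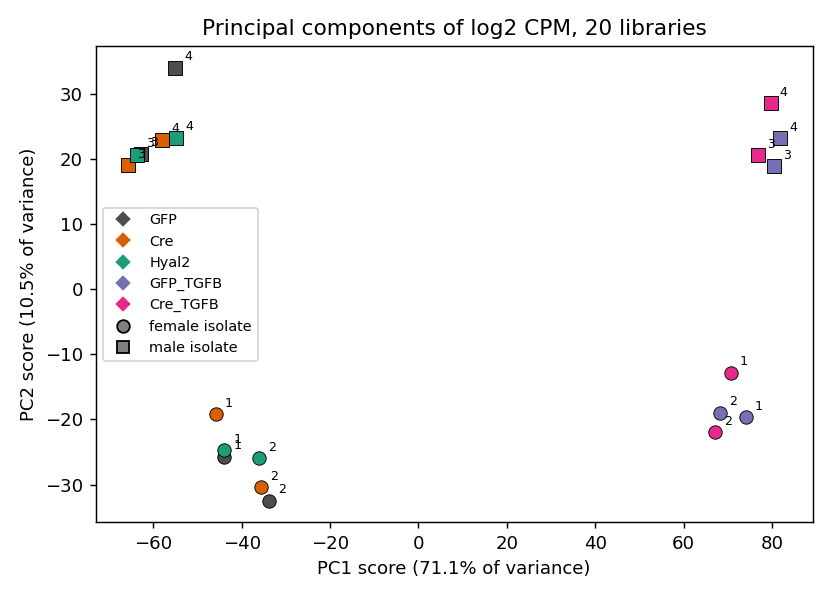
Scores of the 20 libraries on the first principal component (71.1% of variance, x axis) and the second (10.5%, y axis) of log2 CPM, coloured by group, with the marker giving the sex of the isolate. The libraries with TGFB and those without it lie apart along the x axis.

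Hyal2 (ENSMUSG00000010047) encodes a hyaluronidase anchored at the cell surface, an enzyme that cleaves the matrix polysaccharide hyaluronan. It lay at 41.2 ± 3.46 CPM (SD, n = 4) with the GFP virus and at 10.4 ± 2.9 CPM with the Cre virus, a 3.95-fold lower level. With TGFB the level was 36.8 ± 3.9 CPM in GFP_TGFB and 7.42 ± 1.56 CPM in Cre_TGFB (n = 4 each). The overexpression virus gave 934 ± 466 CPM (SD, n = 4), which was 22.7-fold above the GFP virus. Counts of Hyal2 were 1561 to 3212 in the GFP libraries, 428 to 1299 in Cre, 18568 to 62732 in Hyal2, 1308 to 2828 in GFP_TGFB and 207 to 712 in Cre_TGFB. The counts cover the whole gene, so reads from exons outside the deleted one are included.

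**Figure D2:**
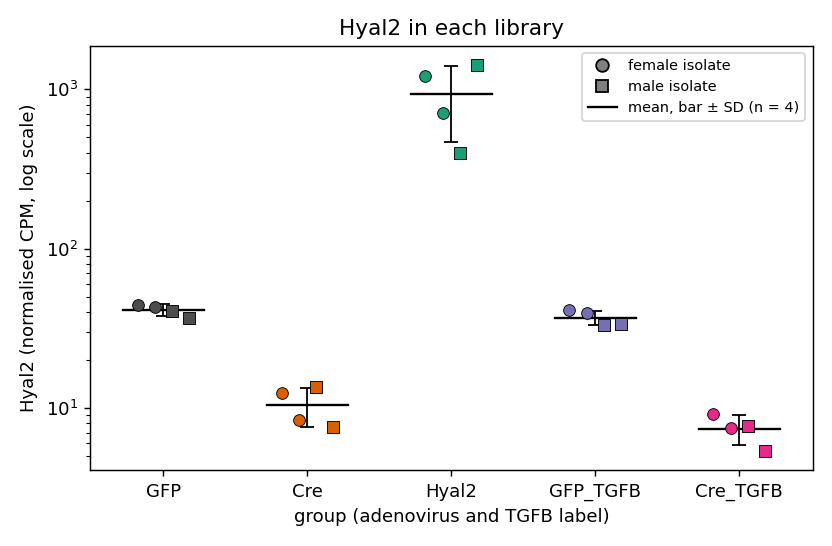
Normalised Hyal2 level in each library (CPM, log scale on the y axis) by group (x axis), with markers for the sex of the isolate, and lines and bars for mean ± SD (n = 4). Means were 41.2 CPM in GFP, 10.4 in Cre, 934 in Hyal2, 36.8 in GFP_TGFB and 7.42 in Cre_TGFB.

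The comparison of Cre with GFP asks what loss of Hyal2 does to fibroblasts without TGFB. Without the replicate block Hyal2 was the 1 gene called, with a log2 fold change of -1.98 (SE 0.28, edgeR adjusted p = 0.0184). With the block, which takes out differences between the paired isolates, edgeR called 42 genes. Interferon-stimulated genes, which are induced during antiviral responses, lay above GFP in all 49 tested members, with a median log2 fold change of 0.89. The antiviral GTPase Mx1 stood at 1.89 ± 0.849 CPM (SD, n = 4) in GFP and 10.3 ± 5.84 in Cre. The nucleotide kinase Cmpk2 stood at 8.36 ± 2.51 and 27.4 ± 11.4 CPM, the chemokine Ccl5 at 1.33 ± 0.32 and 3.68 ± 0.832 CPM, and Ifi35 at 49.0 ± 6.47 and 83.0 ± 17.1 CPM. None of these 4 passed edgeR without the block (adjusted p = 0.256 for Mx1, Cmpk2 and Ifi35, 0.156 for Ccl5), whereas all 4 passed with the replicate block (0.00612 for Mx1, 0.012 for Cmpk2 and Ccl5, 0.0196 for Ifi35).

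Of the 49 interferon-stimulated genes, edgeR called 0 over all genes tested and 44 when adjusted over the list alone. At an unadjusted p under 0.05 the number was 45, limma-voom called 0, DESeq2 called 10, and edgeR with the replicate block called 11. As a set the list rose (camera adjusted p = 6.36e-51, and adjusted p = 0.248 with an estimated correlation), while fry gave an adjusted p of 0.155 and, with the block, 0.0146. The mean paired difference between the isolates' Cre and GFP cultures was 0.97 ± 0.16 (SD, n = 4, log2), above 0 in 4 of 4 isolates. Among markers of other cells, the mean paired difference was -0.01 ± 0.07 (SD, n = 4) for leukocytes, 0.33 ± 0.23 for mesothelium, 0.28 ± 0.19 for cardiomyocytes, 0.20 ± 0.26 for Schwann cells and 0.12 ± 0.11 for pericytes, the last 4 above 0 in 4 of 4 isolates. It was 0.09 ± 0.11 for endothelium and 0.02 ± 0.08 for adipocytes, and camera passed none of these lists without the block.

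Genes of the G2 and M phases of the cell cycle fell as a set, with 36 of 36 members below 0 and a median of -0.24 (camera adjusted p = 0.000183, and adjusted p = 0.723 with an estimated correlation). The checkpoint kinase Bub1b had a log2 fold change of -0.25, the kinetochore gene Nuf2 -0.41 and the proliferation marker Mki67 -0.42, none of them called (edgeR adjusted p = 0.926 each). The mitochondrially encoded mRNAs fell as a set (median -0.46, camera adjusted p = 0.00119, and adjusted p = 0.593 with an estimated correlation), with mt-Co1 at -0.46 and mt-Nd5 at -0.48, and without replicate 4 this set gave 0.121. In both sets edgeR, DESeq2, limma-voom and the block called 0 members, also adjusted over the list alone for edgeR, and at an unadjusted p under 0.05 there were 1 of the G2 and M phase and 2 of the mitochondrial genes. The share of mitochondrially encoded counts was 0.799% ± 0.27 (SD, n = 4) in GFP and 0.588% ± 0.037 in Cre.

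NF-kB inflammatory genes rose as a set, with 28 of 30 members above 0 and a median of 0.13 (camera adjusted p = 0.00138, and adjusted p = 0.48 with an estimated correlation; block fry 0.0146). The chemokines Ccl7 and Ccl2 had log2 fold changes of 0.43 and 0.51 (edgeR adjusted p = 0.604 and 0.647). Glycolysis genes rose as a set (19 of 21 above 0, median 0.13, camera adjusted p = 0.00299, and adjusted p = 0.667 with an estimated correlation; 0.112 without replicate 4), with Pfkp at 0.15 and Hk1 at 0.17. Lysosome genes rose as a set by a median of 0.06 (camera adjusted p = 0.0495, and adjusted p = 0.667 with an estimated correlation), with Galns at 0.16, and gave 0.193, 0.0687 and 0.152 without replicates 1, 3 and 4. Genes beside Hyal2 on its chromosome rose as a set (10 of 14 above 0, median 0.13, camera adjusted p = 0.03, and adjusted p = 0.48 with an estimated correlation). Naa80 was at 0.22 and Nprl2 at 0.15, and the set gave 0.059 without replicate 1 and 0.089 without replicate 4. Its mean paired difference was 0.096 ± 0.022 (SD, n = 4), and 0.072 ± 0.042 for the Hyal2 virus against the same GFP libraries. The rise was thus not particular to the Cre virus. In each of these 4 sets edgeR called 0 members, over all genes and adjusted over the list alone, as did DESeq2, limma-voom and the block over all genes. At an unadjusted p under 0.05 there were 3 members in the NF-kB set, 0 in the glycolysis and lysosome sets and 1 among the neighbours. With the replicate block camera also passed the collagen set (up, 0.0158), the S phase set (down, 0.0177) and the pericyte set (up, 0.0267). With an estimated correlation and the block their adjusted p was 0.426, 0.672 and 0.426.

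Of the hyaluronan genes other than Hyal2, none was called (edgeR adjusted p = 0.918 to 1). The hyaluronan synthase Has2 stood at 40.8 ± 14.7 CPM in GFP and 38.2 ± 10.8 in Cre (SD, n = 4), a log2 fold change of -0.09. Has1 was at -0.03, Has3 at -0.81, the hyaluronidases Hyal1 and Hyal3 at 0.18 and 0.02, and the hyaluronan-degrading Cemip and Cemip2 at 0.07 and -0.13. The genes of precursor supply, Ugdh, Ugp2 and the transporter Slc35d1, were at -0.05, -0.18 and 0.09. Without GFP replicate 2 Has1 was at 1.08 and Has2 at 0.18, neither called (edgeR adjusted p = 0.751 and 0.871). That fit kept Cre replicate 2 of the same isolate, and Has1 was high in both, at 2.79 CPM in GFP and 2.62 in Cre. The shift therefore reflects the broken pair and not a rise with Cre. The list did not pass camera (adjusted p = 0.117).

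Replicates of the groups were separate in 575 genes (3.7%). Chance gives 2.86% for independent libraries, but libraries that share isolates are not independent, so this is no exact reference. The share was 1.2% for Hyal2 against GFP and 1.6% for Cre_TGFB against GFP_TGFB. The number of genes called by edgeR was 1 of 15624, and 711 lay at an unadjusted p under 0.05. DESeq2 called 37, and edgeR with the replicate block called 42 (37 higher and 5 lower), which included Hyal2. The Hyal2 call itself was lost in 7 of the 8 fits that left out 1 library: adjusted p was 0.0745, 0.0695, 0.0623 and 0.0516 without GFP replicates 1 to 4, and 0.0689, 0.106 and 0.0817 without Cre replicates 1, 2 and 4. Its log2 fold change stayed between -1.86 and -2.12 in these fits.

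**Figure D3:**
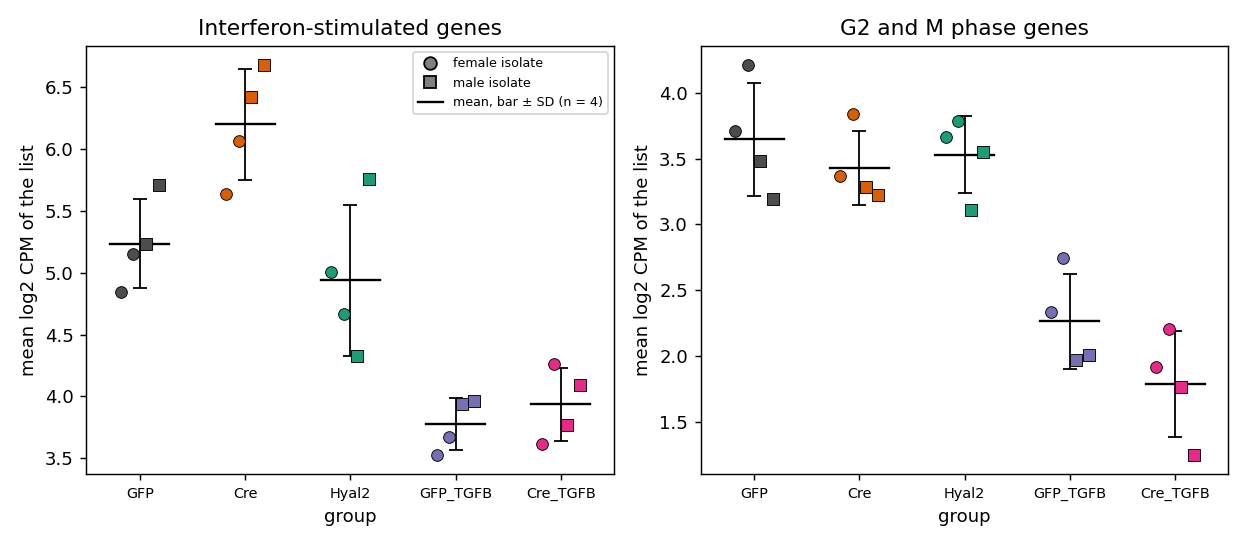
Mean log2 CPM over the interferon-stimulated genes (49) and the G2 and M phase genes (36) in each library (y axis) by group (x axis), with markers for the sex of the isolate, and mean ± SD (n = 4). The paired Cre minus GFP difference of the interferon-stimulated genes was 0.97 ± 0.16, and the paired Cre_TGFB minus GFP_TGFB difference of the G2 and M phase genes was -0.48 ± 0.23.

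The comparison of Hyal2 with GFP asks what added Hyal2 does. Hyal2 rose by a log2 fold change of 4.50 (SE 0.31, edgeR adjusted p = 1.43e-07), and it was the 1 gene called, by DESeq2, limma-voom and the block as well. At an unadjusted p under 0.05 there were 331 genes. Interferon-stimulated genes fell as a set, with 45 of 49 members below 0 and a median of -0.20 (camera adjusted p = 5.7e-08, and adjusted p = 0.827 with an estimated correlation; 0.237 without replicate 3). The mean paired difference was -0.30 ± 0.49 (SD, n = 4), with 2 of 4 isolates below 0. Ifi27l2a stood at 140 ± 33.5 CPM in GFP and 92.7 ± 36.2 in Hyal2, Bst2 at 264 ± 28.4 and 199 ± 77.3, and Ccl5 at 1.33 ± 0.32 and 0.902 ± 0.24 (SD, n = 4), none of them called (edgeR adjusted p = 1). Of the 49, 0 were called by edgeR over all genes or adjusted over the list alone, 0 by DESeq2, limma-voom or the block, and 0 lay at an unadjusted p under 0.05.

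Among the hyaluronan genes, Cemip had a log2 fold change of 0.30, Has1 -0.35, Has2 -0.07, Has3 -0.67, Hyal1 0.11, Hyal3 0.07, Cemip2 -0.10, Slc35d1 0.04, Ugdh -0.12 and Ugp2 -0.14, all with an edgeR adjusted p of 1. Without GFP replicate 2 Has1 was at 0.76 and Has2 at 0.21 (adjusted p = 0.994 each). That fit kept Hyal2 replicate 2 of the same isolate, where Has1 lay at 1.75 CPM, so it breaks a pair. Their list did not pass camera (adjusted p = 0.302); its mean was 0.33 because of Hyal2, and its median -0.07. Of the genes beside Hyal2, Rbm6 was at -0.12 and Nprl2 at 0.12, and the list had a mean paired difference of 0.072 ± 0.042 (SD, n = 4), above 0 in 4 of 4 isolates. With the replicate block 8 more sets passed camera: the leukocyte (0.000154), G2 and M phase (0.00115) and mitochondrially encoded (0.0455) sets fell, and the basement membrane (0.0349), pericyte (0.0349), matricellular (0.0418), mesothelial (0.0455) and myofibroblast (0.0455) sets rose. None of the 8 passed with an estimated correlation and the block (adjusted p = 0.523 to 0.768).

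The comparison of GFP_TGFB with GFP asks how TGFB, the main inducer of myofibroblasts, changes fibroblasts with intact Hyal2. The labels leave open whether the GFP cultures received bFGF in its place. The differences may thus be those of TGFB against bFGF, and effects of the 2 factors cannot be told apart here. The same limit holds for every comparison of cultures with and without TGFB. Of 15624 genes, 8634 were called (4159 higher and 4475 lower), and 2954 of them changed by at least 2-fold (979 higher and 1975 lower). The hormone gene Fgf21 rose from 0.231 ± 0.125 to 22.6 ± 11.3 CPM (SD, n = 4, log2 fold change 6.53, edgeR adjusted p = 2.45e-10), and the cadherin Cdh6 rose by 6.34, the cytoskeletal Add2 by 6.25, the Wnt pathway transcription factor Lef1 by 6.04 and Olfm2 by 5.61. Ptgs2, the inducible prostaglandin synthase, rose from 10.7 ± 7.27 to 458 ± 56.8 CPM. The ferritin receptor Scara5 fell from 11.7 ± 8.11 to 0.0265 ± 0.0209 CPM (log2 fold change -8.66, edgeR adjusted p = 1.21e-06), a level under the counting floor, so that the fitted size of the change depends on the prior count. The chemokine Cxcl5 fell from 46 ± 7.12 to 0.138 ± 0.119 CPM, and Fmo2 changed by -7.04, Abi3bp by -7.00, haptoglobin (Hp) by -6.98 and the progenitor marker Ly6a (Sca-1) by -6.58.

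Myofibroblast contractile genes rose as a set: 17 of 22 rose and 1 fell, or 19 and 1 adjusted over the list alone (median 1.01, camera adjusted p = 6.7e-07, and adjusted p = 0.273 with an estimated correlation). The tropomyosin Tpm1 rose from 541 ± 67.3 to 2444 ± 169 CPM (SD, n = 4), Tpm2 by 1.35, the myosin Myh9 by 1.05 and the filamin Flna by 0.96. Smooth muscle actin, Acta2, chosen after its values were seen, rose from 869 ± 239 to 3732 ± 447 CPM. TGF-beta feedback genes and direct targets rose as a set, with 17 of 24 higher and 5 lower, also adjusted over the list alone (camera adjusted p = 0.000909, and adjusted p = 0.14 with an estimated correlation). Tgfb1 rose by 2.13, the ubiquitin ligase Smurf2 by 1.36 and the NADPH oxidase Nox4 by 2.46, while Tgfbi fell by 4.16 on the log2 scale.

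Resting fibroblast genes fell as a set, with 26 of 29 lower and 1 higher, also adjusted over the list alone (median -2.68, camera adjusted p = 3.71e-10, and adjusted p = 0.273 with an estimated correlation). The receptor Pdgfra fell from 1016 ± 42.8 to 153 ± 10.6 CPM and Mgp from 1318 ± 164 to 114 ± 14.2 (SD, n = 4), and the Wnt antagonist Sfrp1 changed by -2.68. The transcription factor Meox1 was the 1 member that rose, from 10.6 ± 0.72 to 278 ± 50.1 CPM. Small leucine-rich proteoglycans fell as a set, with 9 of 13 lower and 1 higher, or 10 and 1 adjusted over the list alone (median -1.59, camera adjusted p = 0.00383, and adjusted p = 0.273 with an estimated correlation). Prelp changed by -5.90, Podn by -3.72, decorin (Dcn) by -2.03 and lumican (Lum) by -1.80. Matrix proteases and their inhibitors fell as a set, with 20 of 36 lower and 10 higher, also adjusted over the list alone (camera adjusted p = 0.022, and adjusted p = 0.3 with an estimated correlation), and stromelysin, Mmp3, fell from 1792 ± 170 to 95.5 ± 9.46 CPM, Adamts1 by 1.78 and Adamts2 by 2.27 on the log2 scale.

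Interferon-stimulated genes fell as a set, with 40 of 49 lower and 1 higher, or 42 and 1 adjusted over the list alone (median -1.26, camera adjusted p = 9.32e-08, and adjusted p = 0.696 with an estimated correlation). Iigp1 fell from 70.1 ± 23.2 to 2.94 ± 0.286 CPM (SD, n = 4), Ifi27l2a changed by -4.49 and the immunoproteasome subunit Psmb8 by -2.85. NF-kB inflammatory genes fell as a set, with 18 of 30 lower and 5 higher, also adjusted over the list alone (camera adjusted p = 0.00538, and adjusted p = 0.396 with an estimated correlation): Ccl7 changed by -3.02, and the NF-kB inhibitor Tnfaip3 rose by 2.44. Leukocyte markers fell as a set, with 7 of 17 lower, 5 adjusted over the list alone and 16 with the replicate block (camera adjusted p = 0.0389, and adjusted p = 0.696 with an estimated correlation; 0.111 without replicate 2 and 0.0871 without replicate 3). The mannose receptor Mrc1 fell from 10.7 ± 5.96 to 1.38 ± 0.848 CPM, Cd14 by 1.11 and Cd68 by 0.93 on the log2 scale. Mesothelial markers fell as a set, with 7 of 12 lower, also adjusted over the list alone (camera adjusted p = 0.022, and adjusted p = 0.396 with an estimated correlation), among them the retinoic acid enzymes Aldh1a1 (-2.93) and Aldh1a2 (-1.50) and the low-count Upk3b (-3.77).

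Genes of the G2 and M phases fell as a set, with 35 of 36 lower, also adjusted over the list alone (median -1.45, camera adjusted p = 3.02e-09, and adjusted p = 0.696 with an estimated correlation): Bub1b changed by -1.44, Ccnb2 by -1.85 and Nuf2 by -1.81. DNA replication genes fell as a set, with 18 of 41 lower and 2 higher, also adjusted over the list alone (camera adjusted p = 0.0318, and adjusted p = 0.696 with an estimated correlation), including Tk1 (-1.91) and Prim1 (-1.08), and gave 0.0516 without replicate 1 and 0.0755 without replicate 2. The p53 and DNA damage genes rose as a set, with 22 of 36 higher and 9 lower, also adjusted over the list alone (camera adjusted p = 0.022, and adjusted p = 0.14 with an estimated correlation). Among them Pmaip1 rose by 2.96 and Gdf15 by 2.07, while the death receptor Fas fell by 1.21 on the log2 scale.

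**Figure D4:**
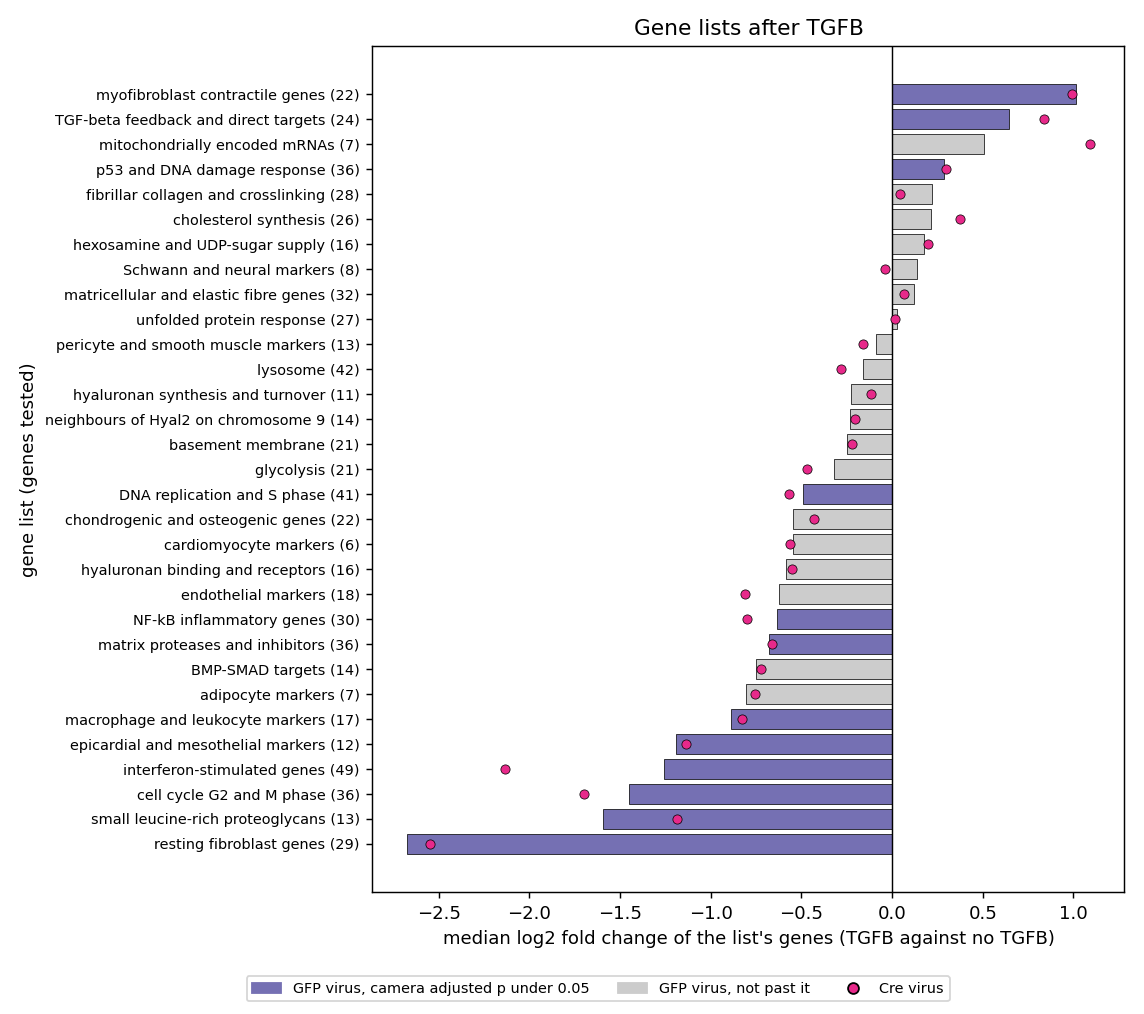
Median log2 fold change with TGFB of each gene list (x axis; lists on the y axis with the number of tested genes), as bars for the GFP virus, coloured where camera passed, and points for the Cre virus. Resting fibroblast genes had a median of -2.68 and contractile genes of 1.01 with the GFP virus.

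Of 11 hyaluronan genes tested, 4 were called with TGFB, and the list did not pass camera (adjusted p = 0.568). The precursor transporter Slc35d1 rose from 10.0 ± 0.629 to 17.4 ± 0.712 CPM (SD, n = 4, edgeR adjusted p = 5.82e-09). Cemip fell from 335 ± 122 to 154 ± 30.2 CPM (adjusted p = 0.00144), Hyal1 from 9.46 ± 1.3 to 6.5 ± 0.24 (0.00248) and Cemip2 from 55.1 ± 7.76 to 43.1 ± 4.91 (0.0033). Has2 stood at 40.8 ± 14.7 and 33.5 ± 5.44 CPM (adjusted p = 0.383), Has1 at 1.09 ± 1.15 and 1.9 ± 0.78 (0.331) and Has3 at 0.304 ± 0.0892 and 0.202 ± 0.0216 (0.11). Hyal2 was at -0.16 (adjusted p = 0.639), Ugdh at -0.19 (0.188), Ugp2 at -0.23 (0.129) and Hyal3 at -0.18 (0.753). Has1 passed with the replicate block (0.00742) and without GFP replicate 2 (0.0214), Ugdh with the block (0.0147) and Has3 without GFP replicate 4 (0.0465). The fit without GFP replicate 2 kept GFP_TGFB replicate 2 of the same isolate, where Has1 lay at 2.99 CPM, so it breaks a pair. Of 16 hyaluronan binding genes, 4 rose and 7 fell (camera adjusted p = 0.254): the receptor Cd44 rose from 98 ± 24.3 to 250 ± 32.7 CPM, while Layn fell by 0.90, Itih2 by 0.96 and Tlr2 by 0.76 on the log2 scale.

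The comparison of Cre_TGFB with GFP_TGFB asks whether loss of Hyal2 alters cells under TGFB. Hyal2 was the 1 gene called (log2 fold change -2.30, SE 0.29, edgeR adjusted p = 0.00286), with 223 genes at an unadjusted p under 0.05 and 2 called by DESeq2. Genes of the G2 and M phases fell as a set, with 36 of 36 members below 0 and a median of -0.47 (camera adjusted p = 2.93e-29, and adjusted p = 0.301 with an estimated correlation; fry 0.799, block fry 0.0331). The mean paired difference was -0.48 ± 0.23 (SD, n = 4), below 0 in 4 of 4 isolates. The mitotic kinesin Kif2c stood at 3 ± 0.714 CPM in GFP_TGFB and 1.66 ± 0.512 in Cre_TGFB, Nuf2 at 2.41 ± 0.772 and 1.54 ± 0.348, and Cenpf at 2.96 ± 1.02 and 1.91 ± 0.664 (SD, n = 4), none of them called (edgeR adjusted p = 1). Of the 36 genes edgeR called 0, DESeq2, limma-voom and the block also called 0, and 10 lay at an unadjusted p under 0.05. Among markers of other cells, the mean paired difference was 0.284 ± 0.207 (SD, n = 4) for mesothelium and 0.084 ± 0.085 for Schwann cells, both above 0 in 4 of 4 isolates. It was 0.019 ± 0.044 for leukocytes, 0.054 ± 0.106 for endothelium and 0.051 ± 0.104 for pericytes. For cardiomyocytes it was 0.005 ± 0.254 and for adipocytes -0.045 ± 0.091.

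DNA replication genes fell as a set, with 40 of 41 below 0 and a median of -0.19 (camera adjusted p = 9.03e-12, and adjusted p = 0.797 with an estimated correlation); the ligase Lig1 had a log2 fold change of -0.31 and Mcm10 of -0.70. Chondrogenic genes rose as a set, with 20 of 22 above 0 and a median of 0.15 (camera adjusted p = 0.0106, and adjusted p = 0.0615 with an estimated correlation; 0.0604 without replicate 1), with Col2a1 at 0.33 and Ank at 0.10. The p53 genes rose as a set by a median of 0.06 (camera adjusted p = 0.0266, and adjusted p = 0.0615 with an estimated correlation), with Ccng1 at 0.14 and Ercc5 at 0.12, and gave 0.0571, 0.0881 and 0.173 without replicates 1, 2 and 4. EdgeR, DESeq2, limma-voom and the block called 0 members of these 3 sets, with 4 DNA replication genes and 0 of the other sets at an unadjusted p under 0.05, and 0 members of any of the 4 sets were called adjusted over the list alone. With the replicate block interferon-stimulated genes passed camera as well (up, 0.0134, and adjusted p = 0.843 with an estimated correlation; paired difference 0.16 ± 0.32, SD, n = 4). Hyal1 stood at 6.5 ± 0.24 CPM in GFP_TGFB and 9 ± 0.438 in Cre_TGFB and was called only when adjusted over the list alone (edgeR adjusted p = 1 over all genes). Has1 was at 0.22, Has2 at 0.06, Has3 at -0.11, Cemip at 0.24, Cemip2 at 0.11, Hyal3 at 0.20, Slc35d1 at 0.05, Ugp2 at -0.07 and Ugdh at -0.00, all with an adjusted p of 1.

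The comparison of Cre_TGFB with Cre asks how TGFB acts after Hyal2 deletion. It called 8832 of 15624 genes (4294 higher and 4538 lower), with 2987 changed by at least 2-fold (962 higher and 2025 lower). Lef1 rose by 7.96, Cdh6 by 6.72, Add2 by 6.56, Fgf21 by 6.06, Olfm2 by 5.54 and the serotonin receptor Htr2b by 5.42. Scara5 changed by -9.66, Cxcl5 by -8.38, Ly6a by -7.20, Hp by -6.81, Fmo2 by -6.64 and A2m by -6.62, the last from 58.7 ± 17 to 0.608 ± 0.186 CPM (SD, n = 4). Scara5 and Lef1 were near the counting floor in their lower group, so their fitted sizes depend on the prior count. Hyal2 was at -0.48 (edgeR adjusted p = 0.157).

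Of the sets, interferon-stimulated genes fell in 48 of 49 members (median -2.14, camera adjusted p = 6.35e-15, and adjusted p = 0.417 with an estimated correlation) and G2 and M phase genes in 36 of 36 (median -1.70; 1.47e-11, and adjusted p = 0.486 with an estimated correlation). Resting fibroblast genes fell in 26 of 29 (median -2.55; 1.64e-10, and adjusted p = 0.293 with an estimated correlation), and contractile genes rose in 18 of 22 (median 0.99; 1.26e-06, and adjusted p = 0.293 with an estimated correlation). Camera also passed the TGF-beta targets (up, 0.000556, and adjusted p = 0.115 with an estimated correlation), NF-kB genes (down, 0.00119; 0.293), S phase genes (down, 0.00323; 0.664), small proteoglycans (down, 0.00708; 0.293), mesothelial markers (down, 0.0155; 0.334), p53 genes (up, 0.0161; 0.115) and proteases (down, 0.0208; 0.293). The second p of each pair is the adjusted p with an estimated correlation. Among these sets 16 TGF-beta targets, 5 NF-kB, 1 S phase, 1 proteoglycan, 20 p53 and 8 protease genes were called higher, and 5, 21, 25, 8, 7 and 20 lower, with 6 mesothelial markers lower. The mitochondrially encoded mRNAs rose in 7 of 7 (median 1.09, camera adjusted p = 0.0197, and adjusted p = 0.562 with an estimated correlation), and lysosome genes fell in 24 of 42 and rose in 10 (0.0272, and adjusted p = 0.562 with an estimated correlation). The remaining 4 calls were lost in some fits. BMP targets (down, camera adjusted p = 0.0272, and adjusted p = 0.562 with an estimated correlation) gave 0.0768 with the replicate block, and glycolysis genes (down, 0.0272, and adjusted p = 0.612 with an estimated correlation) gave 0.0627 without replicate 2. Cholesterol synthesis genes (up, 0.0296, and adjusted p = 0.684 with an estimated correlation) gave 0.0917 without replicate 1 and 0.0854 without replicate 2, and leukocyte markers (down, 0.0311, and adjusted p = 0.712 with an estimated correlation) gave 0.0759 and 0.0832 without replicates 2 and 3. Endothelial markers passed with the block alone (down, 0.022, and adjusted p = 0.322 with an estimated correlation). Adjusted over the list alone, the counts were the same except for NF-kB genes (22 lower), proteoglycans (9 lower) and leukocyte markers (6 lower, 8 over all genes).

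The interaction asks whether the Cre effect differs with TGFB. Interferon-stimulated genes had a lower Cre effect with TGFB than without it in 49 of 49 members (median difference -0.76, camera adjusted p = 7.72e-27, and adjusted p = 0.928 with an estimated correlation), and the paired difference was -0.81 ± 0.43 (SD, n = 4), below 0 in 4 of 4 isolates. Isg15 had a difference of -1.32, Ccl5 of -1.34 and Ifi35 of -0.76. Camera also passed G2 and M phase genes (median -0.23; adjusted p = 0.00129), glycolysis (-0.15, adjusted p 0.0109), lysosome (-0.08, adjusted p 0.0211) and S phase genes (-0.10, adjusted p 0.0468) downward and the mitochondrially encoded mRNAs upward (0.59, adjusted p 0.00117), each with an adjusted p = 0.928 with an estimated correlation. Without replicate 4 these gave 0.536, 0.536, 0.317, 0.67 and 0.184, and without replicate 3 the lysosome set gave 0.0776. With the replicate block the NF-kB (0.0463) and collagen (0.0306) sets passed as well, both downward, with an adjusted p = 0.597 for each with an estimated correlation. No single gene was called over all genes or, in these sets, adjusted over the list alone: edgeR, DESeq2, limma-voom and the block each called 0, and 397 genes lay at an unadjusted p under 0.05, 18 of them interferon-stimulated. Clone names aside, the smallest p belonged to Fam122b (0.68), Stmn4 (2.09) and Hykk (0.48) upward and to Slc25a22 (-0.48), Piwil4 (-0.96) and Ryr1 (-1.93) downward, and Hyal2 was at -0.32, Has1 at 0.25, Has2 at 0.16 and Has3 at 0.70 (all edgeR adjusted p = 1). Without GFP replicate 2 Has1 was at -0.86 (adjusted p = 0.895), in a fit that kept the other libraries of that isolate and so breaks its pairing.

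The sex difference asks whether TGFB acts alike on the female and male isolates, with 2 of each. It was called for 216 genes (145 with a higher effect in males and 71 lower). The stress response genes Ppp1r15a, a phosphatase subunit, and Atf3, a transcription factor, rose more in males: by 2.09 against 0.61 for Ppp1r15a (difference 1.49, SE 0.15, edgeR adjusted p = 0.000526) and by 2.55 against 0.75 for Atf3 (1.80, SE 0.20; 0.000936). The matricellular gene Ccn2 rose by 2.38 in males and 1.14 in females (adjusted p = 0.00316), from means of 1515 and 3069 CPM to 7881 and 6754 CPM (n = 2 each). The largest differences by the naming rule were Htr2b (4.004, adjusted p 0.0364), Rph3a (2.64, adjusted p 0.0341) and Car6 (2.30, adjusted p 0.0179) upward and Steap4 (-2.65, adjusted p 0.00333), Ppp1r3c (-2.27, adjusted p 0.0425) and Eef1a2 (-2.17, adjusted p 0.0222) downward. Htr2b lay at 0.0342 CPM in the male GFP cultures, under the counting floor, so the size and rank of its difference depend on the prior count. Cemip, the hyaluronan-degrading gene, had a log2 fold change of -1.73 in males and -0.39 in females (adjusted p = 0.0107), and Has1 (difference 1.41; 0.43), Has2 (0.49), Has3 (0.52) and Hyal2 (-0.08) were not called.

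Unfolded protein response genes had a higher TGFB effect in males as a set, with 4 of 27 called higher, 8 called with the block, or 7 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.000525, and adjusted p = 0.608 with an estimated correlation). They included Atf4 (difference 0.62, edgeR adjusted p = 0.0121) and the asparagine synthetase Asns (0.63, adjusted p 0.0408). Resting fibroblast genes had a lower effect in males in 26 of 29 members (median difference -0.71, camera adjusted p = 4.83e-08, and adjusted p = 0.608 with an estimated correlation), with 0 called by edgeR, 0 by limma-voom, 8 by DESeq2, 10 by edgeR with the replicate block, 16 at an unadjusted p under 0.05 and 10 adjusted over the list alone. Dpt (-0.86) and Htra3 (-1.22) had edgeR adjusted p of 0.0532 and 0.0679, and of 0.0156 and 0.00165 with the block. Cholesterol synthesis genes were lower in 25 of 26 (median -0.37, 1 called, 8 with the block and 4 adjusted over the list alone, camera adjusted p = 1.5e-06, and adjusted p = 0.608 with an estimated correlation), with Hsd17b7 called (-0.80, edgeR adjusted p = 0.0185) and Sc5d at -0.68 (0.0607, and 0.00624 with the block). Camera also passed small proteoglycans (median -0.76, 1 higher called, 4 called with the block, and 1 higher and 3 lower adjusted over the list alone; adjusted p = 0.0117), with Tsku called higher (0.76, adjusted p 0.0241) and Lum at -0.76 (0.0677, and 0.0459 with the block). It passed BMP targets (-0.52, adjusted p 0.0178), hexosamine supply (0.20, adjusted p 0.0306) and S phase genes (0.21, adjusted p 0.0457). Of the BMP targets edgeR called 0, with 2 by DESeq2, 0 by limma-voom, 3 with the block, 6 at an unadjusted p under 0.05, and 1 higher and 4 lower adjusted over the list alone. Of the hexosamine genes edgeR called 0, with 2 by DESeq2, 0 by limma-voom, 0 with the block, 4 at an unadjusted p under 0.05 and 2 adjusted over the list alone. Of the S phase genes 1 was called, 3 with the block and 2 adjusted over the list alone, with Tyms called (0.82, adjusted p 0.0437) and Mcm2 at 0.75 (0.0785, and 0.00864 with the block). With an estimated correlation the adjusted p was 0.608 for small proteoglycans, BMP targets and hexosamine supply and 0.952 for S phase genes. Ccn3 (-0.93, adjusted p 0.0407) and the hyaluronan binding Tnfaip6 (1.29, adjusted p 0.0333) were called as well.

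The number of genes in the sex difference was 945 with the replicate block, 783 by DESeq2 and 187 by limma-voom, with 2572 at an unadjusted p under 0.05. It was 354, 9, 62 and 94 without GFP replicates 1 to 4, and 6, 18 and 36 without GFP_TGFB replicates 2, 3 and 4, each fit then resting on a lone library in 1 cell whose spread is assumed to be that of the others. Ppp1r15a, Atf3 and Ccn2 passed in all 8 such fits. Steap4 was lost without GFP_TGFB replicate 2 (0.0919) and Cemip without GFP replicate 2 (0.0902) or GFP_TGFB replicates 2 (0.0862) and 4 (0.0543). The other genes named as called were lost in 3 to 7 of the 8 fits, with an adjusted p of at most 0.267. Of the calls, 67.1% were higher in males in the fit without the block, 53.3% with it and 46.9% with no filter (925 genes), where most were lower.

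Across 15624 genes, which are not independent replicates, the TGFB effects with the GFP and the Cre virus correlated at a Pearson r of 0.958 (Spearman 0.923). Of 7391 genes called in both, 7389 had the same direction, 3544 up and 3845 down, where independent lists would share 1143 and 1300. The Cre effects without and with TGFB correlated at 0.136 (Spearman -0.00), and at 0.095, 0.01, 0.218 and 0.148 without replicates 1 to 4. The Cre and Hyal2 effects, which share the 4 GFP libraries, correlated at 0.47, or 0.489 without Hyal2. Unchanged groups simulated against those controls gave 0.504 (0.488 to 0.528 in 20 draws), with a covariance of 0.02 (0.019 to 0.0214) where the observed covariance without Hyal2 was 0.0253. With the controls split between the comparisons r ranged from -0.10 to 0.10, with a mean of 0.02. These 3 relations were the ones computed.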

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

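The tests of the GFP virus and the Cre virus as sources of the interferon difference, and of the spread between isolates, were chosen only after the result was seen.

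Interferon-stimulated genes were higher with the Cre virus than with the GFP virus in cultures without TGFB, and the difference was smaller with TGFB (median of the interaction -0.759). Neither list call held in camera with an estimated correlation (adjusted p = 0.248 for Cre against GFP). Without the block edgeR called 0 of the 49 members in either comparison. With the block it called 11 for Cre against GFP and 0 for the interaction. Library depth does not account for the higher values with Cre, since thinning all libraries to the shallowest one left a median of 0.849 where it had been 0.89. If added Hyal2 does not itself act on these genes, a lowering by the GFP virus would have left the Hyal2 virus cultures above GFP as well. Their paired difference was -0.296 ± 0.494 (SD, n = 4), with 2 isolates above 0 and 2 below, where that of Cre was 0.966. That condition was not tested, and a lowering by added Hyal2 could hide an effect of the GFP virus, so the GFP virus is not excluded. The p53 and DNA damage genes, which a toxic effect of Cre recombinase could raise, had a paired difference of 0.041 ± 0.021 (SD, n = 4). An effect of the Cre virus itself and the loss of Hyal2 cannot be told apart, because no culture received Cre with an intact Hyal2 target, so a link between Hyal2 and these genes remains a hypothesis.

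The TGFB response differed between the sexes in 216 genes, by the test of the difference itself. Depth does not account for most of it, since 182 of the 216 genes were called again after thinning to 38.6 M counts, of 195 called in all. Pairing the 4 isolates in the other possible ways called 0 genes, so 1 of the 3 pairings, the one by sex, gave as many. With 3 pairings chance cannot be excluded, and sex and other differences between isolates cannot be told apart with 2 isolates of each sex. Sex of the animals stays open as a biological explanation that may account for these genes.

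Genes of the G2 and M phases were lower in Cre_TGFB than in GFP_TGFB in 4 of 4 isolates. With an estimated correlation the list did not pass camera, and edgeR, DESeq2, limma-voom and the block called 0 of its 36 members. Depth does not account for the lower values, with a median of -0.464 after thinning where it had been -0.472. Neither does normalisation, with -0.469 as the smaller of the medians under other scaling factors. For the spread between isolates, the exact two-sided sign-flip test of the 4 paired differences decides nothing, because its p = 0.125 is the smallest that 4 pairs allow. The paired difference was -0.48 ± 0.23 (SD, n = 4), and fry gave an adjusted p of 0.0331 with the replicate block and 0.799 without it, so the spread is left open. Slower division without Hyal2 or an effect of the Cre virus may account for it, untested.

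Other lists passed camera in the Cre by TGFB interaction, with medians of -0.233 for G2 and M phase genes, -0.098 for S phase genes, -0.146 for glycolysis, -0.08 for lysosome genes and 0.588 for mitochondrially encoded mRNAs. None passed with an estimated correlation (adjusted p = 0.928 for each), nor without replicate 4 (0.536, 0.67, 0.536, 0.317 and 0.184), and the lysosome list gave 0.0776 without replicate 3. Lists that passed camera in the sex difference of the TGFB effect had median differences, male minus female, of 0.198 for hexosamine and UDP-sugar supply, -0.763 for small leucine-rich proteoglycans, -0.524 for BMP targets, -0.714 for resting fibroblast genes, 0.213 for S phase genes, 0.125 for the unfolded protein response and -0.371 for cholesterol synthesis. None of these 7 passed with an estimated correlation (adjusted p = 0.952 for S phase genes and 0.608 for the others), and 0 passed with fry.

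Of 80 groups of 4 libraries tested over 16 measures, 5 held a library far from the other 3, where chance gives about 1 in 20. GFP replicate 2 had 71 M counts (the others 41.9 to 43.4) and GFP_TGFB replicate 2 had 72.1 M (38.6 to 43.3). GFP replicate 4 had a mitochondrially encoded share of 1.2% (0.625 to 0.72). Ugp2 lay at 128 CPM in GFP replicate 4 (92.4 to 97.8) and at 96.5 CPM in Cre replicate 2 (88.3 to 89).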

How the results depend on the processing

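The tests that left Hyal2 out of the correlations, all alternatives for the correlation of the TGFB effects, and the look at the genes behind small counts were chosen only after the result was seen. No called named gene and no called list changed direction under the alternatives run for it, but the balance of counts did. Of the 104 named calls, 104 held with RLE factors, DESeq2, the replicate block, and library sizes without Hyal2 and mitochondrial genes. Limma-voom lost 6, no filter 2 and the fit of only the groups compared 1. Leaving out a library lost 84 of 832 values, none of them in the TGFB effects of the GFP or Cre cultures.

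For Cre against GFP the number of genes was 5 with no filter, 42 with the replicate block, 37 with DESeq2 and 2 with only the groups compared, and 0 to 1 when libraries were left out (1 without Cre replicate 3, 0 without any of the other 7). The 1 gene called was lower, while 37 of the 42 and 34 of the 37 were higher. The 5 without a filter were Sstr5, Gm19410, Stmn4, Ccl5 and Slc25a22, and Hyal2 was not among them (adjusted p = 0.0851). Stmn4 had 6 to 23 counts in GFP, 1 to 4 in Cre and 0 to 2 in Hyal2. Gm19410 had 17 to 30, 1 to 5 and 4 to 13, so for both genes counts below GFP were not particular to the Cre virus. With TGFB the counts of both genes overlapped between the GFP and Cre viruses. For Cre_TGFB against GFP_TGFB the number of genes was 2 with DESeq2, which added Gsta4, and 2 with only the groups compared, which added Gsta3. It was 1 to 2 when libraries were left out (2 without GFP_TGFB replicate 3, again with Gsta4). Without a filter Sstr5 was the 1 gene called, and Hyal2 had an adjusted p of 0.0629. For the sex difference, with 145 genes higher and 71 lower, it was 925 with no filter (434 higher and 491 lower), 945 with the replicate block, 783 with DESeq2, and 6 (without GFP_TGFB replicate 2) to 354 (without GFP replicate 1) when libraries were left out. The cause of these changes was not tested. All other counts stayed within 1.5 times the reported one.

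The correlation of the TGFB effects was 0.981 over genes of at least 5 CPM and 0.937 to 0.952 without 1 replicate number. That of the Cre effects without and with TGFB was 0.01 (without replicate 2) to 0.218 (without replicate 3). Over genes of at least 5 CPM it was 0.059 (Spearman -0.131). The correlation of the Cre and Hyal2 effects was 0.352 over those genes (Spearman 0.666), and 0.414 to 0.552 without 1 replicate number. Both correlations of Cre effects could not be computed over called genes alone, since too few were called. The replicate block, whose pairing comes from a culture identifier that the labels share across groups, changed no call of the named genes or lists other than those given beside the results and in the next sentence. It called 11 named genes that were not called without it, and kept 46 of 47 list calls. Of 54 list calls 0 held with an estimated correlation (adjusted p = 0.0615 to 0.952) and 28 with fry. Leaving out a replicate number kept 161 of 188 list values.

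The 8 libraries of a comparison can be split in 35 ways. For GFP_TGFB against GFP (8634, highest other 0) and for Cre_TGFB against Cre (8832, highest other 0) only the real split called as many genes, a share of 0.029. The 35 splits are equally likely by chance only for independent libraries, and these share isolates, so the share does not by itself exclude chance. In both, the 7 other splits that part all pairs of an isolate called 0 genes, but they are too few to exclude chance by themselves. For Cre against GFP 2 splits, for Hyal2 against GFP 3 and for Cre_TGFB against GFP_TGFB 3 called at least the real 1 gene, so chance cannot be excluded by the count. The highest others, 2822, 2391 and 842, were the splits by sex, which points to the structure of the isolates. Of the 7 other splits that part all pairs as the real one does, the highest called 0, 0 and 1. For the interaction the real count was 0, which all 100 draws reach by construction, so they decide nothing (highest other 572).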

Other observations

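The comparison of the genes called with the replicate block, the virus marker, and the sex differences in levels and in the Cre cultures were tests chosen only after the result was seen.

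With TGFB the collagen genes went both ways: 11 of 28 fibrillar collagen and crosslinking genes rose and 8 fell (12 and 8 adjusted over the list alone), and the set did not pass camera (adjusted p = 0.377). Col1a1, the main chain of type I collagen, rose from 10990 ± 1933 to 19080 ± 2197 CPM (SD, n = 4), while Col3a1, the chain of type III collagen, fell from 26630 ± 6487 to 7061 ± 906 CPM. The crosslinking enzymes Loxl2 and Loxl3 rose by 1.32 and 1.05, and the hydroxylase P4ha3 changed by -1.36. Of 32 matricellular and elastic fibre genes 13 rose and 11 fell (camera adjusted p = 0.647): tenascin C (Tnc) rose from 385 ± 107 to 5525 ± 714 CPM, Ltbp2 rose by 3.11 and periostin (Postn) by 0.70, whereas Ccn3 changed by -4.85 and Ccn5 by -3.47. The BMP targets Id1, Id3 and Atoh8 changed by -1.58, -1.92 and -3.33, and their list had a camera adjusted p of 0.0507.

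Other lists did not pass camera with TGFB in GFP cultures. These were hexosamine supply (7 of 16 higher and 2 lower, camera adjusted p = 0.182), basement membrane (6 higher and 9 lower of 21, 0.53), the unfolded protein response (7 higher and 4 lower of 27, 0.27), lysosome (8 higher and 19 lower of 42, 0.182) and chondrogenic genes (8 higher and 9 lower of 22, 0.416). Among markers of other cells, pericyte (0.933), cardiomyocyte (0.933), Schwann cell (0.824) and adipocyte (0.27) lists did not pass either. Cholesterol synthesis (0.0543, and 0.0281 with the replicate block), glycolysis (0.169 and 0.0419) and endothelial markers (0.0962 and 0.0356) passed with the block alone. With an estimated correlation and the block their adjusted p was 0.642, 0.64 and 0.328.

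With the replicate block 42 genes were called for Cre against GFP, 26 of them also by DESeq2, and 11 were on the list of interferon-stimulated genes (Fisher's exact test, one-sided, p = 3.44e-19). That test counts genes as independent and uses the same libraries, so it adds no separate evidence for the rise of the list. With an estimated correlation the list did not pass camera (adjusted p = 0.248). Among the genes higher with the block, chosen after their values were seen, were the chemokine Cxcl10 (log2 fold change 2.12, adjusted p = 0.0495) and the GTPase Gbp5 (1.29, 0.00612). Among the lower ones was the endothelin receptor Ednrb (-1.65, 0.012).

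Sstr5, a somatostatin receptor, had 3 to 24 counts in each of the 8 libraries with the GFP virus and 0 to 2 in the other 12. It was the 1 gene that separated the libraries in this way. Without a filter edgeR gave an adjusted p of 0.0209 for Cre against GFP, 0.0373 for Cre_TGFB against GFP_TGFB and 0.987 for Hyal2 against GFP. The sequence of the virus was not used here, so it was not tested whether these counts come from the Sstr5 gene or from the virus.

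Of the 216 genes whose TGFB effect differed between the sexes, 216 had a difference of the same direction in the Cre cultures of the same isolates, and 16 passed the threshold there, of 20 in all. The differences in the GFP and Cre cultures correlated at 0.388 across genes, which are not independent replicates. For 148 of the 216 genes the sexes differed more without TGFB than with it, with a median absolute log2 difference of 0.496 without and 0.267 with TGFB.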
